A study of Bacillus subtilis with 4 samples.

How the data were processed

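Gene expression in *Bacillus subtilis* was compared between a depletion strain and its wild type on 4 two-colour arrays of 60-nucleotide oligonucleotides, labelled with Alexa Fluor 555 and 647. Per the labels, the depletion strain carries a dCas9 protein that xylose induces, aimed at the phosphatases of undecaprenyl pyrophosphate, the spent form of the lipid carrier of cell wall synthesis. A preculture at an OD600 of about 0.4 was diluted 100-fold into 50 ml of LB, and xylose was added to 2% in 1 flask of each strain after 1.5 h. Cells were collected 2.5 h later, and the labels give an RNA quality number of 10. Each growth condition, untreated or xylose, has 2 arrays with exchanged dyes. In replicate 1 the depletion strain carried dye 647, and in replicate 2 dye 555, so the dye orientation and the replicate cannot be separated within a condition.

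The labels conflict on replication. The design text calls the arrays of a pair independently grown replicates, while the extraction text speaks of 4 RNA samples in all and of cDNA split between the dyes. The tests follow the design text. If the pairs shared extracts, n = 2 counts arrays and the p-values of single genes measure only the spread between arrays, not between cultures.

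The deposited table holds 1 value per gene and array for 4106 gene symbols, of which 4101 have a value on all 4 arrays. The labels give no unit. The deposited values were read as the log10 ratio of the channel intensities, because 10 raised to the value was a ratio of whole numbers, the smaller at most 1000, for 74.8% to 80.6% of the nonzero values of an array (within 6e-10 on the log10 scale), against 0.0% to 0.4% for base 2 or base e. They were multiplied to the log2 scale and used as deposited, since every array's median lies within 0.1 of 0. Background correction, normalization, the analysis software and the genome build are not given in the sources used here. The direction of the ratio is not stated either. Both orientations of each swap already point the same way, and the direction was taken as depletion strain over wild type because uppP and bcrC, the known phosphatases, were low on all 4 arrays. Gene symbols are those of the table, with the current symbol where it differs, and neighbouring genes were taken from a public annotation whose symbols matched 3036 of the 4106.

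The smallest whole numbers that give each ratio serve as a lower estimate of the channel intensities. Values with no such pair up to a smaller number of 20000 (126 of 16419) were treated as bright. In at most 2469 of the 16419 values a channel lay at the floor of 2 units, and ratios at the floor depend on it. The count is an upper bound, because equal channels and other simple ratios also reduce to such small numbers. After the values were seen, genes with a geometric mean of the 8 recovered channel values of at least 100 were set apart as bright (2480 genes, 60.5%), and all tests were repeated on them and with 50 units added to both channels. The signal over background limits the precision, and so does the number of arrays.

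The strain ratio was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 1 mean per growth condition, a spread shared by both conditions (2 residual degrees of freedom, 1.27 prior degrees of freedom over all genes and 3.91 over bright genes), and Benjamini-Hochberg adjustment at 0.05 over 4101 genes. A gene "rose" or "fell" when its strain ratio passed this test, which does not show in which strain the level moved. The contrasts were untreated, xylose, and the difference of the strain ratios, xylose minus untreated. Gene lists were tested with limma's camera at its preset correlation of 0.01 and with an estimated correlation, adjusted over the 29 lists with at least 3 measured genes. At the preset correlation camera compares the genes of a list with the other genes. Those list p-values rest on the spread between genes, not between arrays or cultures, and treat the genes as nearly independent. With an estimated correlation camera's test has only the 2 residual degrees of freedom, so a call lost there does not measure correlation alone. Member counts are given over all genes and adjusted over the list alone. Genes at least 2-fold changed the same way on both arrays of a condition were counted beside the number expected if the arrays were independent. Tests, gene lists, contrasts and the rule for named genes were chosen before the data were examined.

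The lists were UPP phosphatases, construct loci and xylose use, the SigM, SigW and SigX regulons, SigV and SigY, the Lia system, Bce-type transporters, genes activated and genes repressed by WalRK, peptidoglycan, isoprenoid and undecaprenyl, wall teichoic acid and lipoteichoic acid synthesis, division and shape, SigD, SigB, heat shock, ribosomal proteins, ATP synthase and respiration, CcpA catabolite genes, PhoPR, competence, biofilm matrix, early sporulation, SOS, the PBSX prophage, Fur, purine and pyrimidine synthesis, and fatty acid synthesis. The lists overlap: 20 of the 43 measured SigM members stand in another list too.

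Genes were named by rule: all UPP phosphatases and construct loci; the 12 largest rises and 12 largest falls past the test with the same sign on both arrays; in contrasts with fewer than 10 calls the 10 largest on each side among genes 2-fold changed on both arrays, as values; and up to 4 members per list with the largest mean change. The list members named in the text were taken from these and, where few members of a list passed the test, also from those members, chosen after their values were seen.

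Alternatives were a dye term, centring, scaling between arrays, a robust prior, each condition alone, genes with at least 1 value per condition, a minimum fold of 1.5 (treat), other fold thresholds, leaving out each array, bright genes alone, bright genes with a dye term, and 50 units added. The pipeline was tested on simulated data with known changes planted in 200 genes. At the spread of these arrays it called 0%, 18%, 58% and 80% of planted log2 changes of 1, 2, 4 and 6 over all genes, and 46%, 94%, 100% and 100% over bright genes. In those tests 4 and 5 unchanged genes were called. On genes simulated without correlation, camera called the 1 shifted list and 0 of 29 unshifted ones. False calls in correlated lists were not tested, and real lists had estimated correlations of up to 0.705 (ribosomal proteins). Recovery of whole numbers was right for 100% of 3346 simulated values with the smaller number at most 1000 and for 98.98% of all simulated values. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.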

Results

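The 4 arrays compare a *Bacillus subtilis* depletion strain, in which xylose induces dCas9 against undecaprenyl pyrophosphate (UPP) phosphatases, with its wild type, 2 without xylose and 2 with 2% xylose. They gave 4102 and 4106 values untreated and 4106 and 4105 with xylose. The SD of the log2 ratio over genes was 1.42 and 1.39 untreated and 2.14 and 1.70 with xylose. A channel was counted at the floor of 2 units for at most 21.4% and 7.9% of untreated values and 22.1% and 8.7% with xylose. Across genes, which are not independent replicates, the swapped arrays correlated at r = 0.178 untreated and 0.538 with xylose over all genes. Over the 2480 bright genes r was 0.769 and 0.881. Positive values below mean more transcript in the depletion strain, a direction inferred from the phosphatase genes themselves; the opposite direction would turn every rise into a fall.

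**Figure D1:**
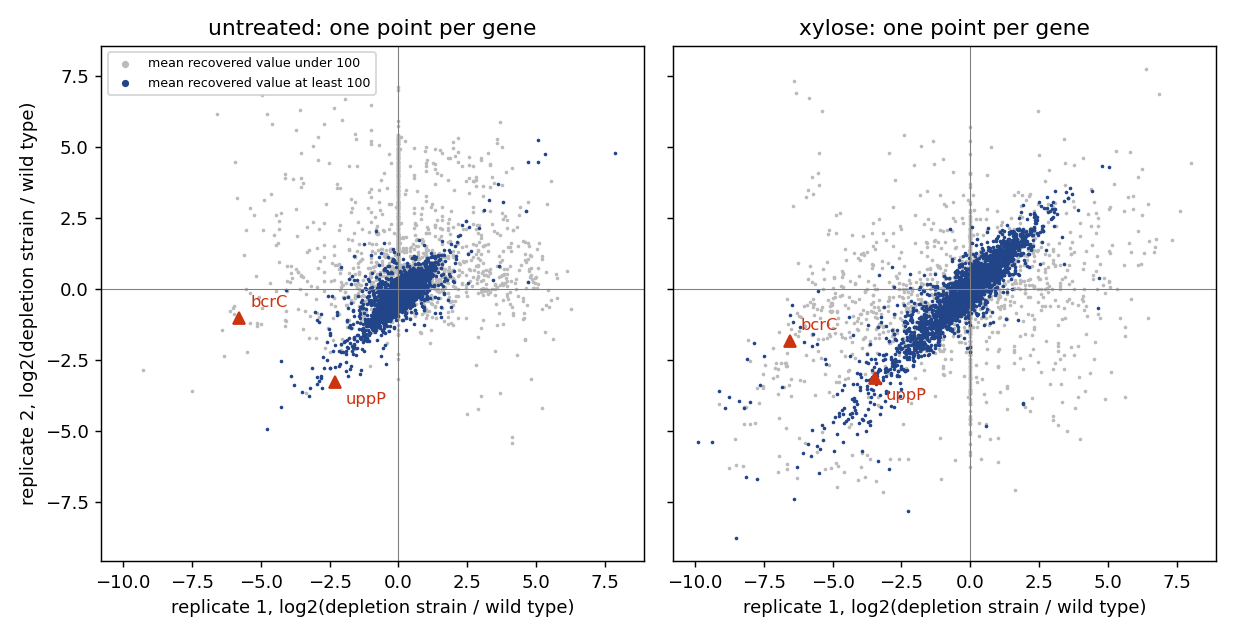
Log2 ratio of depletion strain to wild type on replicate 2 against replicate 1, for untreated and xylose cultures, 1 point per gene. Bright genes (blue) follow the diagonal (r = 0.769 untreated, 0.881 with xylose), dim genes (grey) scatter widely, and triangles mark uppP and bcrC, low on all 4 arrays.

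The direction of the ratio was chosen from the targeted genes, so their being low is not a result of its own. uppP (listed as yubB), which encodes a UPP phosphatase, fell 9.76-fold with xylose (log2 -3.29 ± 0.24, SD, n = 2, adjusted p = 0.0252). Untreated, its log2 ratio was -2.79 ± 0.67 (n = 2, adjusted p = 0.17), which passed over bright genes (adjusted p = 0.00391). bcrC (listed as ywoA), the other main UPP phosphatase, had log2 ratios of -6.55 and -1.83 with xylose and -5.78 and -1.02 untreated, a dim gene at the floor on 1 xylose array that passed no test (adjusted p = 0.21 and 0.486). yodM, a proposed UPP phosphatase, gave 0.34 with xylose and -0.22 untreated. The list of UPP phosphatases was not called (camera adjusted p = 0.303, 1 of 3 down both over all genes and adjusted over the list alone). Untreated it was not called either (adjusted p = 0.0797), but it was with a dye term (adjusted p = 0.0171), without either xylose array (0.0496) and with 50 units added (0.0317).

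Genes at common integration sites and of xylose use were lower in the depletion strain with xylose. In this list 5 of 8 members fell, 6 adjusted over the list alone (median log2 -2.80, camera adjusted p = 0.00645; adjusted p = 0.459 with an estimated correlation). The members that fell were ganA (listed as lacA, a beta-galactosidase, log2 -2.68), amyE (alpha-amylase, -1.91), xynB (xylosidase, -4.80), xylA (xylose isomerase, -2.92) and xylB (xylulokinase, -3.37). The transport genes xynP and araE gave -4.85 (adjusted p = 0.0599) and -2.28 (adjusted p = 0.154), and the repressor gene xylR 0.40 (adjusted p = 0.3). Untreated, xylA and xylB were already at -2.09 and -3.38, values that passed over bright genes (adjusted p = 0.0276 and 0.00867). Of the 8 members 5 were negative on both untreated arrays and 1 positive, amyE (0.73), which is also in the CcpA catabolite list. The list's difference, xylose minus untreated, was not called (median -2.37, camera adjusted p = 0.093).

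With xylose, which by the labels induces dCas9, most SigM genes rose and most carbon catabolite genes fell. SigM is the sigma factor of the response to cell wall antibiotics: 33 of its 43 measured genes rose and 0 fell, with a median of 4.61-fold. Of 54 measured CcpA-controlled carbon use genes, 32 fell and 1 rose (median log2 -3.87). Ribosomal protein genes rose (24 of 47), and genes of iron uptake (16 of 27), motility (15 of 39) and pyrimidine synthesis fell. In all, limma called 757 genes, 301 up and 456 down, and 644 of them were bright. No gene was called with a dye term, with scaling between arrays, or without any 1 of the arrays (unadjusted p under 0.05 in 1660, 1091 and 916 to 1337 genes), while 1386 of the 2480 bright genes were called (619 up, 767 down). For list calls, camera adjusted p = 0.459 with an estimated correlation applies wherever no other value is given.

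**Figure D2:**
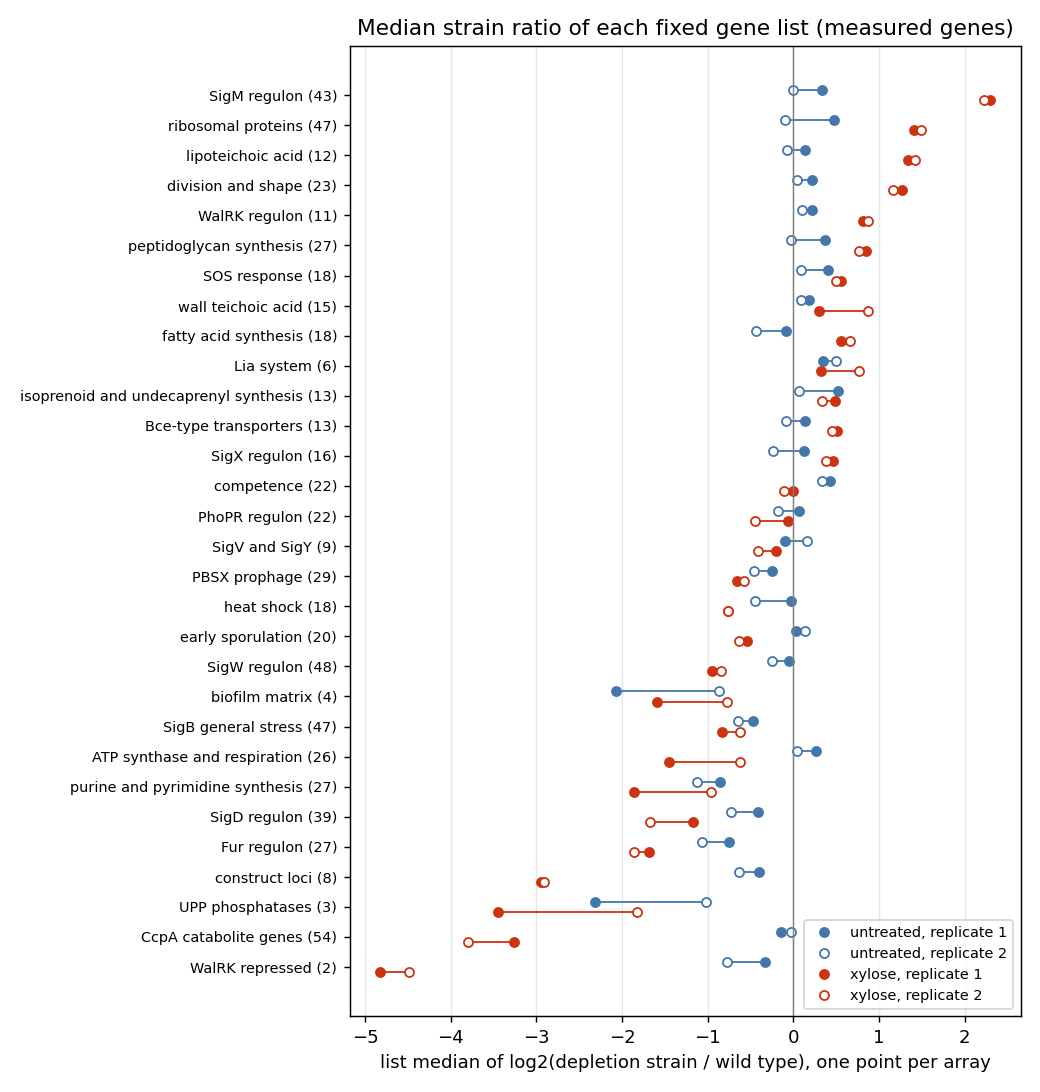
Median log2 ratio of depletion strain to wild type of each gene list on each of the 4 arrays. With xylose the SigM list lies at 2.20 and the CcpA list at -3.87 for gene means, against 0.15 and -0.06 untreated.

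Most SigM genes and a part of the wall synthesis genes rose. The SigM list passed with camera adjusted p = 2.78e-15 (35 up adjusted over the list alone; adjusted p = 0.459 with an estimated correlation). sigM itself rose by log2 3.52 ± 0.24 (SD, n = 2), its anti-sigma gene yhdL by 3.45 and yhdK by 2.38. murG and murB, which encode steps of lipid II synthesis, rose by 3.39 ± 0.24 and 3.25, rodA, for the elongation polymerase, by 2.89, and amj (listed as ydaH), for an alternative lipid II flippase, by 4.56 ± 0.31. ltaSA (listed as yfnI), for a lipoteichoic acid synthase, rose by 2.77 ± 0.06. Members without a call over all genes included ypuA (-5.95 and 3.27 on the 2 arrays, dim), murF at -0.72 and tagU at -0.63. Over bright genes 32 of the 38 bright SigM members were called up and 2 down. Of 27 peptidoglycan synthesis genes 10 rose and 0 fell, and adjusted over the list alone 13 rose and 1 fell (median 0.81, adjusted p = 0.000147; adjusted p = 0.459 with an estimated correlation). Among them pbpA, for a transpeptidase of elongation, rose by 2.96. Over bright genes 15 of the 27 peptidoglycan synthesis genes were called up and 2 down.

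Some genes of division, teichoic acids and the WalRK regulon also rose, and over all genes none in these lists fell. The division and teichoic acid lists share members with the SigM list, among them minD, ltaSA, tagT and tagV. Outside the SigM list, 17 of 58 genes of the peptidoglycan, teichoic acid and division lists rose and 0 fell. Over bright genes 7 wall teichoic acid genes were called up and 1 down. Of 23 division and shape genes 12 rose and 0 fell, 16 adjusted over the list alone (median 1.22, adjusted p = 7.81e-08). mreBH, an actin homologue, rose by 4.67 ± 0.52 and minD, of division site placement, by 2.50. Lipoteichoic acid genes rose in 5 of 12 cases, 7 adjusted over the list alone (median 1.36, adjusted p = 5.27e-05), namely ltaSA and the D-alanylation genes dltA (1.37), dltB (1.41), dltC (1.57) and dltE (1.91). Wall teichoic acid genes rose in 5 of 15 cases, 7 adjusted over the list alone (median 0.71, adjusted p = 0.0102), namely the glycan ligase genes tagT and tagV (listed as ywtF and yvhJ, 2.88 and 1.73), the exporter genes tagG and tagH (1.41 and 1.25) and tagB (1.08). Without xylose replicate 2 this list was at 0.30 and not called (adjusted p = 0.0723). WalRK-activated genes rose in 2 of 11 cases, 7 adjusted over the list alone (median 0.85, adjusted p = 0.000147), namely ydjM (5.25 ± 1.40) and walJ (listed as yycJ, 1.38). For each of these 4 lists, adjusted p = 0.459 with an estimated correlation. Of the genes WalR represses, iseA (listed as yoeB), an inhibitor of autolysins, fell (log2 -5.69 ± 0.32, n = 2), as did pdaC (listed as yjeA), a wall deacetylase (-3.63 ± 0.15); with 2 genes the list was not tested.

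Ribosomal protein genes rose, with a few genes of lipid precursors. Among 47 ribosomal protein genes 24 rose and 0 fell, 44 adjusted over the list alone (median 1.49, adjusted p = 5.51e-16). rplR rose by log2 2.19 ± 0.17 (n = 2), rplE by 2.11 and rplX by 1.91. From untreated to xylose, the ribosomal list's median percentile of recovered intensity moved by -0.2 and 0.0 points in the depletion channel. In the wild-type channel it moved by -2.5 and -2.0, if the ratio's direction is right. At 98.5 to 99.0 the depletion channel had little room to rise. Of 18 fatty acid synthesis genes 3 rose, the initiating enzyme genes fabHB (1.91) and fabHA (1.58) and the desaturase gene des (1.05); adjusted over the list alone 8 rose and 1 fell (median 0.53, adjusted p = 0.00434). Isoprenoid and undecaprenyl synthesis genes rose in 4 of 13 cases, also 4 adjusted over the list alone (median 0.49, adjusted p = 0.00434), namely ispD (listed as yacM, 1.87), ispF (yacN, 1.73), ispE (1.56) and ispH (yqfP, 1.53). In the SOS list, lexA rose (1.52), 1 of 18, and 0 adjusted over the list alone (median 0.71, adjusted p = 0.00952). These 4 list calls were lost as well: adjusted p = 0.459 with an estimated correlation.

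Among the tested lists, CcpA carbon use genes had the lowest median with xylose. The CcpA list passed with camera adjusted p = 3.61e-13, and adjusted over the list alone 42 of 54 fell and 1 rose (adjusted p = 0.459 with an estimated correlation). Among those that fell were rbsD of ribose use (log2 -8.62 ± 0.17, SD, n = 2), bglH of beta-glucoside use (-7.37 ± 1.09), and levE and levG of fructose uptake (-7.53 and -7.24, each at the floor on 1 array). The member that rose was glpD, for glycerol-3-phosphate dehydrogenase (2.70), though its untreated ratio, given below, was higher still. Outside this list glpT, for glycerol-3-phosphate uptake, also fell (-7.23 ± 0.76). Of 26 measured genes of ATP synthase and respiration 10 fell and 1 rose, and 12 and 1 adjusted over the list alone (median -1.27, adjusted p = 0.00434; adjusted p = 0.459 with an estimated correlation). The falls were 5 of 8 ATP synthase genes, with atpE at -1.67 and atpF at -1.56, all 3 genes of the cytochrome bc complex, with qcrB at -3.49, and sdhA and sdhC of succinate dehydrogenase (-3.51 and -3.29). None of the 4 qox and 4 cta genes, of terminal oxidases, passed limma, while cydD, of a transporter for cytochrome bd assembly, rose (2.44). The qox median was 0.23, but the cta median was -1.37, near the -1.51 of the ATP synthase genes, so the missing call does not set cta apart. Without xylose replicate 1 this list was at -0.62 and not called (adjusted p = 0.0829).

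**Figure D3:**
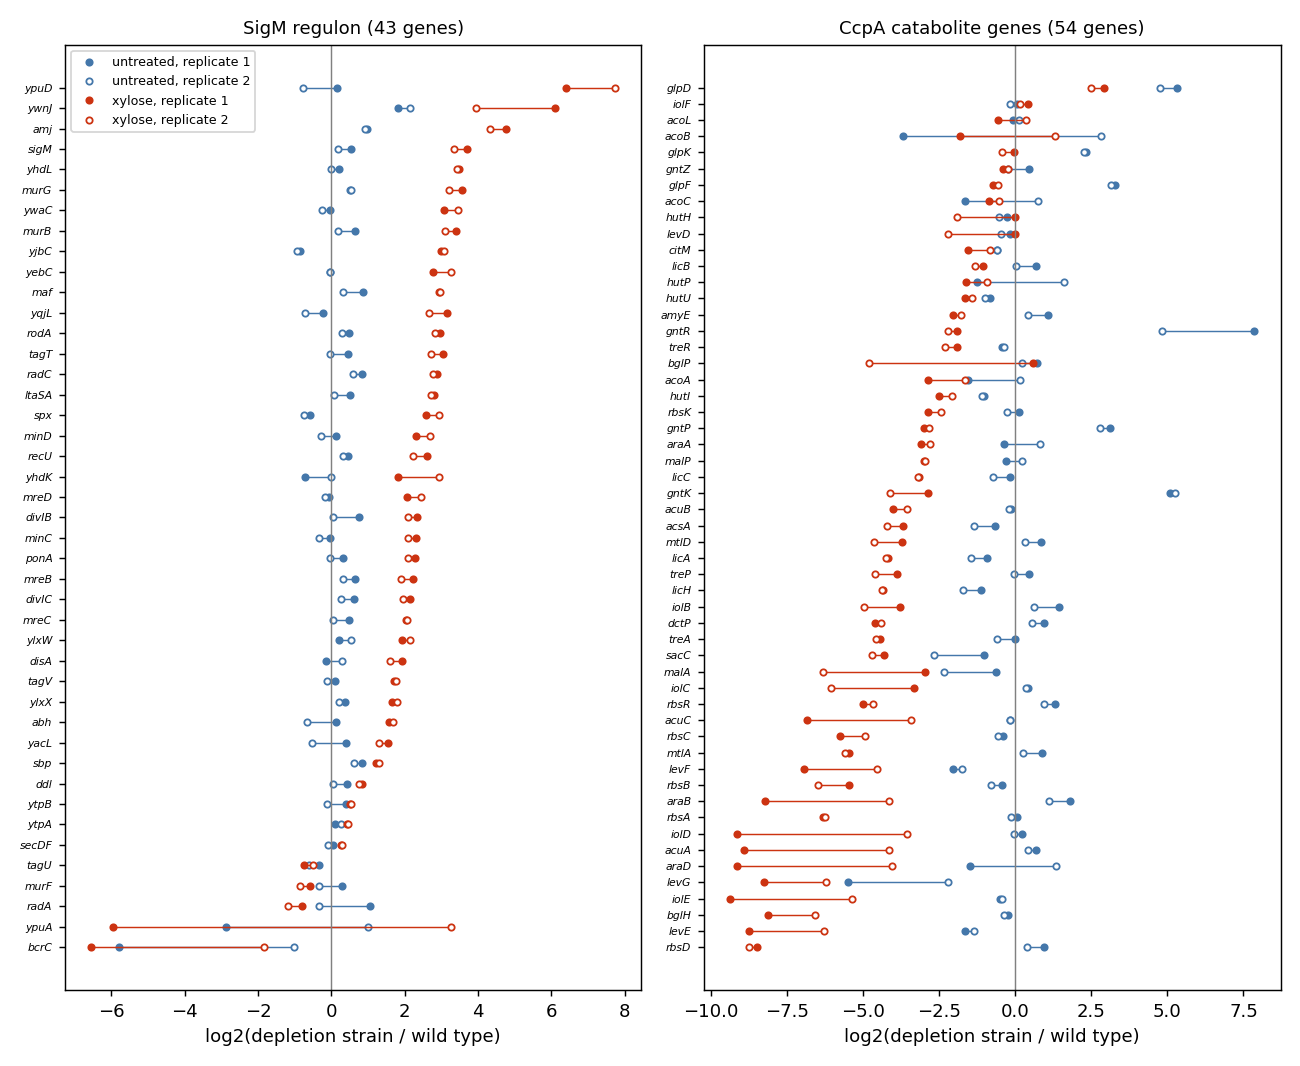
Log2 ratio of depletion strain to wild type for every measured member of the SigM list and the CcpA list on each array. Untreated medians lie at 0.15 and -0.06 for gene means, and with xylose 33 of 43 SigM members rose and 32 of 54 CcpA members fell.

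Genes of iron uptake, motility and pyrimidine synthesis were among those that fell. In the Fur regulon 16 of 27 fell, 21 adjusted over the list alone (median -1.84, adjusted p = 1.3e-08), among them the bacillibactin genes dhbE and dhbC (log2 -4.56 and -4.38) and the siderophore receptor gene feuA (-4.34). In the SigD regulon 15 of 39 fell, 27 adjusted over the list alone (median -1.45, adjusted p = 4.08e-08), among them the autolysin gene lytD (-2.77), the flagellar gene fliF (-2.38) and motA, of the flagellar motor (-2.25). Of 27 purine and pyrimidine genes 11 fell and 1 rose, 12 and 1 adjusted over the list alone (median -1.42, adjusted p = 2.49e-05). All 10 pyr genes of the list, for pyrimidine synthesis and uptake, fell, with pyrAA at -5.92, pyrAB at -5.82 and pyrB at -5.53, against 1 of 13 pur genes, purA (-1.80), and the rise was in the purine transporter gene pbuG (1.46). This split was made after the values were seen and holds over all genes only. Over bright genes 11 of 15 genes with the stem pur were called down and 1 up, against 11 of 12 down with the stem pyr. For all 3 lists adjusted p = 0.459 with an estimated correlation. From untreated to xylose, the median percentile of recovered intensity was lower in both channels for Fur and SigD. It moved by -12.4 and -5.0 points (depletion) and -7.0 and -1.4 (wild type) for Fur. For SigD it moved by -14.8 and -17.5 (depletion) and -8.3 and -7.6 (wild type).

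The SigW, SigB, PBSX and heat shock lists had negative medians. Of 48 SigW genes, a regulon induced by membrane-active agents, 15 fell and 1 rose, 22 and 5 adjusted over the list alone (median -0.84, adjusted p = 0.000316), among the falls yknX and yknW of a transporter operon (-2.82 and -2.75). The SigW gene that rose was yceH (1.34), of an operon shared with other stress sigma factors. SigB general stress genes fell in 7 of 47 cases with 1 rise, 6 and 1 adjusted over the list alone (median -1.05, adjusted p = 0.0102), and the rise was in trxA, for thioredoxin (2.26). The SigB list was not called over bright genes (median -0.56, adjusted p = 0.102). In the PBSX prophage 0 of 29 genes passed limma over all genes (median -0.62, adjusted p = 0.00215), while over bright genes 14 of 26 were called down. For these 3 lists adjusted p = 0.459 with an estimated correlation. Heat shock genes fell in 7 of 18 cases, 8 with 1 rise adjusted over the list alone (median -0.75, adjusted p = 0.0115; adjusted p = 0.516 with an estimated correlation), among the falls clpE of a protease (-2.41) and the chaperonin gene groES (-2.24).

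The remaining lists were not called with xylose, although single members were. In SigX, a regulon of surface charge, 5 of 16 rose and 2 fell (median 0.41, adjusted p = 0.158), the rises being dltA, dltB, dltC, dltE and the regulator gene abh (1.64), and the falls csbB (-2.38) and yfhO (-3.54). In the SigV and SigY list, sigV rose by 2.77 ± 0.13 and oatA (listed as yrhL), of peptidoglycan acetylation, by 2.80, 2 of 9 (median -0.36, adjusted p = 0.831). The Lia system, which answers lipid II antibiotics, had 1 of 6 up, liaH at 1.11 ± 0.14 (median 0.52, adjusted p = 0.0563). Of 13 genes of Bce-type transporters, for peptide antibiotics, yxdJ rose by 1.18 (median 0.48, adjusted p = 0.0608). With a dye term the Bce-type list was called (adjusted p = 0.0458), and without xylose replicate 1 the Lia list was (adjusted p = 0.0258). In PhoPR, of phosphate starvation, 4 of 22 fell, namely glpQ (-5.33), pstBB (-3.32) and the regulator genes phoP and phoR (-2.91 and -2.66). The median was -0.13 (adjusted p = 0.361). In competence comEB rose (1.69) and comS and dprA (listed as smf) fell (-1.65 and -1.50), of 22 genes (median -0.06, adjusted p = 0.811); here and for SigV and SigY camera's direction was up against a negative median, a difference of sign among median, mean and test found in 10 of 87 list tests, 0 of them called. In early sporulation spoVE rose (1.21) and spoIIAA, spoIIIAA and kinA fell (-6.71, -5.79 and -1.87), of 20 genes (median -0.75, adjusted p = 0.187), and in biofilm matrix 0 of 4 passed limma (median -1.04, adjusted p = 0.187).

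Among the largest rises with xylose beyond those named, ypuD, a SigM member, reached log2 7.07 ± 0.95, ykuE 6.86 ± 0.02, ykpC, which lies beside mreBH, 6.23 ± 2.52, yisQ 5.08 ± 0.28 and ywnJ, beside bcrC, 5.03 ± 1.52 (n = 2 each). yodL, yonJ, yhzC and yvsG rose by 3.95 to 4.48. The size of several of these rests on a wild-type channel at the floor: with 50 units added, ykuE was at 2.07, yisQ at 0.94, yonJ at 0.52, ywnJ at 2.14, ydjM at 2.19 and ypuD at 3.07. The largest falls further included gltP, for glutamate uptake (log2 -7.63 ± 3.20), iolE of inositol use (-7.36), glnM (-7.35), ywsB (-6.90 ± 0.70), ybbF (-6.90), spoIIAA, of the sporulation sigma F switch (-6.71), and yyaB (-6.50). glnM, spoIIAA and yyaB were at the floor on both xylose arrays, and with 50 units added they stood at -2.59, -1.98 and -1.46. gltP, iolE and ybbF were at the floor on 1 array, and gave -4.04, -4.59 and -2.34.

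Without xylose, where uppP was already low, the lists of iron uptake, motility and nucleotide synthesis had lower values in the depletion strain, the last through its purine genes, and no single gene passed. The Fur regulon had a median log2 of -0.85 (camera adjusted p = 1.12e-15; adjusted p = 0.759 with an estimated correlation), with 15 of 27 down adjusted over the list alone. Its genes dhbB and dhbF, of bacillibactin synthesis, were at -3.56 ± 0.08 and -3.48 (n = 2, adjusted p = 0.112 and 0.113). The SigD regulon had a median of -0.53 (adjusted p = 2.32e-08; adjusted p = 0.759 with an estimated correlation), with the flagellin gene hag at -1.13. Purine and pyrimidine genes had a median of -0.91 (adjusted p = 0.000226; adjusted p = 0.795 with an estimated correlation), 14 down and 4 up adjusted over the list alone. Its 13 pur genes, of purine synthesis, had a median of -1.56, with purQ at -2.27, while its 10 pyr genes, of pyrimidine synthesis, had 0.11, with pyrR at -2.16 but pyrE and pyrF, of the last steps, at 2.43 and 2.38; this split was made after the values were seen.

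Of the other lists called untreated, all with lower medians, biofilm matrix had -1.77 over 4 genes (adjusted p = 0.0415; adjusted p = 0.759 with an estimated correlation), with tasA, its amyloid fibre gene, at -1.70. SigB was at -0.57 (adjusted p = 0.000226; adjusted p = 0.759 with an estimated correlation) and PBSX at -0.37 (adjusted p = 0.000226; adjusted p = 0.795 with an estimated correlation). Heat shock was at -0.26 (adjusted p = 0.00896) and fatty acid synthesis at -0.28 (adjusted p = 0.0343), both with adjusted p = 0.84 with an estimated correlation, with groEL at -1.65 and fabHB at -1.13. SigW was at -0.17 (adjusted p = 0.0343; adjusted p = 0.903 with an estimated correlation). The heat shock, fatty acid and SigW calls were lost over bright genes (adjusted p = 0.0984, 0.229 and 0.317) and without untreated replicate 2 (adjusted p = 0.281, 0.281 and 0.334). The biofilm call was lost without either untreated array (adjusted p = 0.123 and 0.0561). The SigM list was at 0.15 (adjusted p = 0.344) and ribosomal proteins at 0.23 (adjusted p = 0.17), neither called over all genes. Over bright genes both were called (0.19 with adjusted p = 0.0282, and 0.23 with adjusted p = 0.0158), as were peptidoglycan synthesis (0.15, adjusted p = 0.0212), the Lia system (0.43, adjusted p = 0.0343) and construct loci (-0.94, adjusted p = 0.017). The SigM, ribosomal and peptidoglycan medians were positive on replicate 1 alone: the medians of all members on the arrays were 0.33 and 0.00 for SigM, 0.47 and -0.10 for ribosomal proteins and 0.37 and -0.03 for peptidoglycan synthesis. For these 5 lists over bright genes, adjusted p = 0.884 with an estimated correlation.

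Among the 10 largest positive untreated values, 5 were of bright genes. gntR and gntK, of gluconate use, had log2 ratios of 6.34 ± 2.15 and 5.16 ± 0.12, glpD 5.05 ± 0.40, and manA and manP, of mannose use, 4.78 ± 0.43 and 4.60 ± 0.14 (n = 2 each). Over bright genes all 5 passed (adjusted p = 0.00436, 0.000877, 0.000562, 0.000562 and 0.000562). The dim genes ywdC, yocC, yrkN, spoVAB and ydaQ gave values of 4.37 to 4.80. The CcpA list of carbon use genes was not called untreated (median -0.06, adjusted p = 0.846, with 18 members positive and 22 negative on both arrays). The largest negative values were yxeP (-6.06) and yxeQ (-5.53), both dim, ysfD (-4.86 ± 0.11) and ysfC (-4.20 ± 0.07), for glycolate oxidase subunits, then yneN (-3.59 ± 0.29) and dhbB, with yhjN (-4.34), yuxI (-3.92), levG (-3.85) and ywjC (-3.52) dim. Over all genes limma called 0 genes untreated, with 598 at an unadjusted p under 0.05. Scaling between arrays gave 15 calls, and over bright genes 273 passed (80 up, 193 down), a count that was 15 without either untreated array and 519 without either xylose array.

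The difference of the strain ratios between the growth conditions, which asks whether the strains differed by another amount with xylose than without, was positive for SigM genes and negative for carbon use genes. The median difference, xylose minus untreated, was log2 2.04 for the SigM list (adjusted p = 5.01e-18), 1.30 for ribosomal proteins (adjusted p = 8.52e-17) and -3.29 for CcpA genes (adjusted p = 1.42e-15). For these 3 lists adjusted p = 0.61 with an estimated correlation. Of 29 lists 13 were called, 8 of them up and 5 down. mreBH differed by 4.38 ± 0.42 (SE) and amj by 3.61, and fabHB by 3.03. rbsD differed by -9.29 ± 0.35, gntK by -8.65 ± 0.55 and glpT by -8.27 ± 0.49.

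Further large positive differences were in ypuD (7.39), yhjN (7.54), ykpC (5.26), ykuE (5.11), yjbE (4.89), ylaH (4.66), yjdF (4.58), ydjM (4.29) and yonJ (4.03), all of them dim genes. Further large negative ones were in the sporulation gene spoIIIAA (-9.40), gltP (-8.55), gntR (-8.40), yhdC (-8.25), the peptide transporter gene appF (-7.99), ybbD (-7.97) and gutP, of glucitol uptake (-7.84), of which gltP and gntR were bright. uppP differed by -0.49 (adjusted p = 0.556) and bcrC by -0.79 (adjusted p = 0.874). Over all genes limma called 0 differences, with 1001 at an unadjusted p under 0.05; over bright genes 756 passed (337 up, 419 down; 286 and 288 without untreated replicate 1 or 2), among them mreBH, rbsD, gntK, gntR, gltP and glpT.

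Counted without a test, 1190 genes were at least 2-fold changed the same way on both xylose arrays, 458 up and 732 down, against 147.2 and 290.8 expected from independent arrays. Untreated, 402 genes met this, 238 up and 164 down, against 111.5 and 34.7. Opposite 2-fold changes on the swapped arrays occurred in 151 genes with xylose and 127 untreated. Among bright genes, 803 with xylose (312 up, 491 down) and 174 untreated met the criterion, with 4 and 2 in opposite directions. The untreated split turned over there, to 44 up and 130 down, and with 50 units added to 36 up and 116 down, so the excess of positive genes untreated lay among dim ones.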

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

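The tests of dye bias, of the rise shared by wall genes and of the match of the untreated arrays were chosen after the results were seen, as was the bright-gene threshold; the others were written down before.

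The strain ratio differed between the growth conditions for 13 gene lists, by the camera test of the difference itself (xylose minus untreated, median log2). The differences were 2.04 for SigM, 1.30 for ribosomal proteins, 1.26 for lipoteichoic acid, 0.98 for division and shape, 0.75 for WalRK and 0.71 for fatty acid synthesis. They were 0.50 for peptidoglycan synthesis and 0.25 for wall teichoic acid. Negative differences were -3.29 for CcpA genes, -1.70 for respiration, -0.84 for SigW, -0.83 for SigD and -0.59 for Fur. None of the 13 was called with an estimated correlation (adjusted p from 0.61 to 0.691). Without single arrays some calls were lost: Fur without untreated replicate 1 or either xylose array (adjusted p from 0.0617 to 0.147), SigD without untreated replicate 1 or xylose replicate 2 (0.0623 and 0.0552), wall teichoic acid without the same ones (0.0783 and 0.133), and SigW without xylose replicate 1 (0.0956).

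Some named genes had opposite signs in the 2 conditions on every array, while limma's test of the difference over all genes called none of them. The difference, xylose minus untreated, was log2 -9.40 for spoIIIAA, -9.29 for rbsD, -8.65 for gntK, -8.55 for gltP, -8.40 for gntR, -8.27 for glpT and -8.25 for yhdC. It was -7.99 for appF, -7.84 for gutP, -7.45 for ydaQ, -6.95 for pyrF, -6.68 for pyrE, -6.28 for glpQ and -6.21 for pyrAB. It was -5.09 for manA, -4.80 for manP, -4.19 for manR, -3.85 for glpF, -2.64 for amyE, -2.54 for glpK, -2.18 for dprA, -1.99 for atpE and -1.95 for atpF. Positive differences were 7.54 for yhjN, 3.03 for fabHB, 2.93 for trxA, 2.10 for dltE, 1.85 for pbuG, 1.48 for tagH, 1.34 for xylR, 1.34 for yubA and 1.20 for des. Among these genes spoIIIAA, yhdC, appF, gutP, ydaQ and yhjN were dim, so the size of their differences may depend on the floor. Genes whose difference passed over bright genes included rbsD, gntK, gntR, gltP and glpT.

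The CcpA list was low with xylose. Dim spots are argued against, since bright members had a median of -4.08, and so is dye bias, since both orientations were low (-3.26 and -3.80). In the wild-type channel the list's median percentile was higher with xylose than untreated by 18.7 and 19.8 points, and in the depletion channel it was lower by 19.4 and 13.5, so a wild-type level that rose between conditions may account for part of the ratio; with the ratio in the opposite direction the channels would change places. Whether the strains were at different stages of nutrient use cannot be told apart from a strain effect, because CodY-repressed genes, also raised when nutrients run out, had a median of -0.71 (-1.46 and -0.53 on the arrays, -0.29 over bright genes), between the values either case required (6.63% of matched random lists were as low). An effect of depletion on carbon use stays open and was not tested apart from growth.

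The SigM list was high with xylose. Bright members had a median of 2.20, which argues against dim spots, and both dye orientations were high (2.22 and 2.29), which argues against dye bias. A rise shared by all wall and division genes is argued against as the whole cause: SigM members lay 1.53 above 58 other wall and division genes, themselves at a median of 0.71 with 17 up and 0 down (permutation p = 2e-05, two-sided, the smallest that 100000 resamples can give). That p counts genes as independent, though the SigM list had an estimated correlation of 0.254. It does not measure the spread between arrays or cultures. Depletion, xylose, dCas9 induction and growth remain open and were not tested apart. The mean ratio of uppP was nearly as low untreated (difference -0.49), while the SigM list was at 0.15 there. That difference was not called by limma (adjusted p = 0.556), but limma called 0 differences over all genes, so this does not show equal depletion. If the ratio's direction is right, the SigM list's median percentile moved by 13.4 and 11.1 points in the depletion channel. In the wild-type channel it then moved by 0.0 and -0.7.

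The untreated arrays matched poorly over all genes (r = 0.178 across genes). Over bright genes r was 0.769, consistent with dim spots as a source of the mismatch. The difference between the swapped arrays correlated between the conditions at 0.348 over bright genes, consistent with some gene-specific dye bias as well. Because dye and replicate coincide, a difference between cultures stays open, and no biological explanation was tested.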

How the results depend on the processing

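The tests over bright genes, alone, with a dye term or without an array, and those with 50 units added were chosen after the data were seen; all others were planned. Centring, a robust prior and genes with at least 1 value per condition gave 650 to 748 xylose calls against 757, and 0 untreated and 0 differences by limma. The xylose count was 0 with a dye term, scaled between arrays, or on its own 2 arrays (1660, 1091 and 1337 genes at an unadjusted p under 0.05), and 333 at a minimum fold of 1.5. Over bright genes it was 1386, with 50 units added 1386 and over bright genes with a dye term 1671. The untreated count was 15 when scaled, 273 over bright genes, 78 with 50 units added and 703 over bright genes with a dye term, and the difference count was 756, 560 and 1175 in the latter 3. Leaving out each array gave 0 to 1311 xylose calls, 0 to 519 untreated and 0 to 789 differences, with 0 over all genes. Over bright genes alone these were 1135 to 1311, 15 (without either untreated array) to 519 (without either xylose array), and 286 to 789. The fits with a dye term, on 2 arrays or without an array have fewer degrees of freedom, and a minimum fold asks for larger changes; for scaling and for the added calls the cause was not tested.

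With an estimated correlation 0 gene lists were called in each contrast, over all genes and over bright genes. That setting also leaves camera 2 residual degrees of freedom, so a lost call cannot be laid to correlation alone. Construct loci with xylose had an estimated correlation of -0.09, below the preset, and still went from camera adjusted p = 0.00645 to 0.459. The untreated CcpA list, not called, turned from -0.06 to a median of 0.10 over bright genes, with or without a dye term, so the gene filter turned it; it was called only with the dye term (adjusted p = 0.00341). Other medians not called in either setting also turned over bright genes: Bce-type transporters (with xylose 0.48 to -0.05, untreated 0.02 to -0.17), PhoPR and early sporulation untreated (0.02 to -0.22 and 0.34 to -0.09) and the differences of SigB (-0.28 to 0.17) and of biofilm matrix (0.18 to -0.66, 2 bright genes). Untreated genes changed on both arrays numbered 775 at 1.5-fold, 186 at 3-fold, 174 over bright genes and 152 with 50 units added, against 402, and with xylose 652 at 3-fold against 1190. Over bright genes with a dye term, list calls lost against the main test numbered 3 with xylose, 4 untreated and 2 of the difference. Those gained numbered 0, 1 (beside the CcpA list) and 1. Over all alternatives, named genes and lists stayed on their side of the threshold in 5393 results, passed it newly in 813 and lost it in 784, and in 1, the CcpA list, a result past the threshold had the opposite direction.

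The planned median or single probes of a gene were not run, since the table has 1 row per gene, and averaging each pair to 1 replicate leaves the same means with no test. Dim signal limits the ratios: up to 2469 of 16419 values rest on a channel at the floor of 2 units.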

Other observations

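The tests here were chosen after the results were seen.

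Genes that share the symbol stems als and cys changed outside the fixed lists; the scan tested stems, not pathways. In a scan of 122 families of gene symbols with at least 4 members (244 Fisher's exact tests, 16 past Benjamini-Hochberg adjustment, 2 of them wholly outside the lists), 3 of 4 als genes rose with xylose (adjusted p = 0.0273). alsT, and alsD and alsS of acetoin synthesis, rose by log2 1.94, 1.79 and 1.78, and untreated the family had a median of 1.30. Of 6 genes with the stem cys 4 fell (adjusted p = 0.0299), namely cysC (log2 -2.95), cysK (-2.72), cysP (-2.34) and cysH (-1.85), with an untreated median of -0.97. Genes within an operon are not independent. On data with planted families, every member called among independent random calls, the scan found 10 of 10, with 0 of 234 others. That does not cover families called in part or genes that share an operon, so it lends no weight to the als and cys calls.

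Of the genes beside uppP and bcrC, 1 neighbour of each rose. yubA, a neighbour of uppP, rose by log2 1.18 ± 0.04 with xylose (n = 2, adjusted p = 0.039), and ywnJ, a neighbour of bcrC and a member of the SigM list, by 5.03 (2.14 with 50 units added). On the other side, yubC gave 5.63 and -1.32 on the xylose arrays and nrgB -0.78 ± 0.12 (adjusted p = 0.0724), which passed no test over all genes. Other glycerol and mannose genes, named after their values were seen, had positive untreated log2 ratios that passed no test over all genes: glpF was at 3.21, glpK at 2.29 and manR at 3.70, while citB, for aconitase, was at -3.33.

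Over bright genes, of 193 that fell untreated 135 also fell with xylose and 9 rose. Of 80 that rose untreated 33 also rose with xylose and 25 fell. No chance level is given, since both comparisons share each gene's spread and the dye orientations. The untreated calls numbered 15 without either untreated array and 519 without either xylose array, against 273.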
